A study of Homo sapiens with 18 samples.

How the data were processed

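RNA was extracted from skin at 18 injected sites of 6 donors, and per the labels' protocols the libraries of the 3 single-injection donors were made with the TruSeq Stranded Total RNA kit and those of the 3 fractionated donors with the Ovation RNA-Seq System V2. The authors deposited, per sample, RSEM tables of isoforms on hg38, and the submitters' processing notes name CASAVA 1.8.4, STAR, RSEM and DESeq2; their roles and the other versions are not given in the sources used here. The unit used here is the expected count per isoform that the authors deposited, an estimated count that need not be whole because RSEM divides reads among isoforms and near-identical genes. The deposited TPM values and effective lengths served only to weight the isoforms of a gene.

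Expected counts of 51918 isoforms were summed over 26467 genes and rounded to whole numbers. Genes on the Y chromosome and 2 X-inactivation genes, 115 in all, were left out of every table, which left 26352, and 25188 symbols matched a RefSeq table of GRCh38.p14 that supplied coordinates. Total expected counts per library were 29562164 to 45370904 in the single-injection donors and 6410529 to 15050550 in the fractionated donors, so genes of low level rest on fewer counts in the latter. No pair of libraries of a group was alike within sampling noise (chi-square per degree of freedom of 25.3 or more in 18 pairs).

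Groups came from the treatment named in the labels, and the donor from the sample titles. Donor entered each fit as a block, since the 3 sites of a donor are not independent; deviations from group means correlated between sites of a donor at a median of 0.727 in the single-injection donors (lowest 0.590) and 0.199 in the fractionated donors (lowest 0.0419). Genes were tested with edgeR's quasi-likelihood test with TMM normalization, filterByExpr and robust fitting (edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 3 main comparisons were sole versus vehicle, scalp versus vehicle and sole versus scalp over all donors. The same comparisons within each schedule, and their differences between schedules, came from a fit with site effects per schedule. That fit shared 1 estimate of the spread over all 18 libraries. Vehicle sites of the 2 schedules were compared without a block. KRT9 was tested also with an exact two-sided sign-flip permutation test over the 64 sign patterns of 6 donors. Designs, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from 3 alternatives on ribosomal RNA added afterwards.

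Of 30 gene lists for skin cell types and states, 29 with at least 3 measured members were tested with camera at a preset correlation of 0.01 (limma 3.58.1), again with an estimated correlation, and with fry; the list of mitochondrially encoded genes had no symbol in the tables. Counts adjusted over the list alone apply Benjamini-Hochberg to the members only. The rule named, per main comparison, KRT9, up to 8 genes per direction past the threshold with at least 1 CPM and the same direction in at least 5 of 6 donors, up to 4 members with the smallest p of each list that passed or had members that passed over the list alone, and up to 3 members of the volar keratin, distal HOX and WNT lists; the text gives a part of these. In the fit by schedule it named up to 5 genes per direction past the threshold, which gave GTF2IP4. GTF2IP4 in the comparisons over all donors, LCE1C, SPARC, DCN and the genes of the vehicle sites were chosen after their values were seen.

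The steps were tested on simulated counts drawn from the real means and library sizes, with 200 genes of at least 1 CPM changed. The spread was its trend over expression level in the libraries of both kits. Spread particular to a gene, a kit or the ribosomal RNA share was left out, so the shares called need not hold in these data. For sole versus vehicle over all donors, tested on 17394 genes, 31.3% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 100% of those changed 4-fold were called, with 5 unchanged genes called. In the single-injection donors the shares were 10.4%, 59.7% and 97.0%, and in the fractionated donors 14.9%, 53.7% and 83.3%, over 17500 genes. A simulated list of 22 genes lowered by 0.4 on the log2 scale passed with a preset correlation (adjusted p = 2.8e-10) and with an estimated one (adjusted p = 6.2e-04). Simulated genes vary independently, which real members of a list do not.

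Alternatives were DESeq2 size factors, no filter and a filter of 1 CPM in 6 libraries, DESeq2 1.42.0, limma voom with sample quality weights, offsets from effective lengths, library kit in place of the donor block, only the libraries compared, an adjusted p under 0.1, other set tests, Pearson correlation, and each donor left out in turn. Folds against near-0 groups used a floor of 3 counts over the group. Intervals and floors cover counting error or the spread between these libraries only. No genome sequence was used here, so GC content was not examined.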

Results

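Gene expression was measured by RNA sequencing of skin from 6 donors whose own cultured fibroblasts had been placed in the dermis of non-volar skin. Volar skin is the thick, hairless skin of palms and soles, and KRT9 encodes a keratin typical of its upper epidermal layers. Each donor had 1 site given medium alone (vehicle), 1 given scalp fibroblasts and 1 given sole fibroblasts, sampled 5 months later. In 3 donors each cell site received 10000000 cells in 1 injection (single injection), and in the other 3 donors it received 3 injections of 3330000 cells (fractionated injections). The labels thus give 6 groups of 3 libraries, 18 in all, with the donor shared by the 3 sites. Libraries of the single-injection donors were made with a stranded total RNA kit and held 29562164 to 45370904 expected counts, of which 10.8% to 18.8% fell on ribosomal RNA. Libraries of the fractionated donors were made with an amplification kit and held 6410529 to 15050550 expected counts, of which 1.07% to 51.7% fell on ribosomal RNA. Schedule, kit and donors therefore changed together, whereas differences between sites of the same donor were taken within 1 kit. That removes a constant difference between kits, and not differences between libraries of a kit such as the ribosomal RNA share.

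The first question was whether sites given sole fibroblasts expressed KRT9 above sites given medium or scalp fibroblasts. KRT9 (chromosome 17, 41565836 to 41572059, GRCh38.p14, protein coding) was expressed at a low level in every library, with 13 to 81 counts per library and a mean of 2.13 CPM ± 1.15 (SD, n = 18). In the single-injection donors it stood at 1.28 CPM ± 0.546 (SD, n = 3) at vehicle sites, 1.32 ± 0.514 at scalp fibroblast sites and 1.31 ± 0.299 at sole fibroblast sites. In the fractionated donors the values were 2.72 ± 1.45, 3.20 ± 0.526 and 2.96 ± 1.37 CPM. The log2 fold change between sole fibroblast and vehicle sites was 0.12 ± 0.24 (SE), with a 95% interval of -0.40 to 0.63, or 0.760-fold to 1.55-fold. KRT9 was higher at the sole fibroblast site in 5 of 6 donors (edgeR p = 0.638; exact two-sided sign-flip permutation p = 0.188, where the smallest possible p is 0.0313). Against scalp fibroblast sites the log2 fold change was -0.07 ± 0.25 (SE), with 3 of 6 donors higher (edgeR p = 0.772; exact sign-flip p = 0.844). At scalp fibroblast sites it was 0.19 ± 0.25 (SE) relative to vehicle, with 2 of 6 donors higher (edgeR p = 0.454; exact sign-flip p = 0.688). None of these differences passed a test. Both comparisons with scalp fibroblast sites changed direction without replicate 2 of the fractionated groups, to 0.12 for sole versus scalp and -0.037 for scalp versus vehicle.

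**Figure D1:**
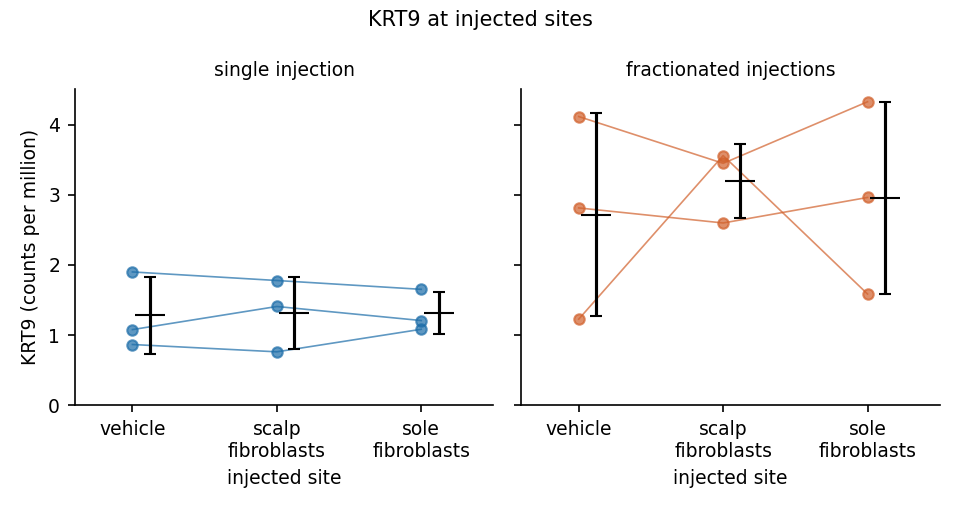
KRT9 in CPM at vehicle, scalp fibroblast and sole fibroblast sites, for the single-injection donors (left) and the fractionated donors (right). Points are libraries, lines join the sites of 1 donor, and black marks give the mean ± SD of 3 libraries. The sole fibroblast means were 1.31 and 2.96 CPM and the vehicle means 1.28 and 2.72 CPM. The SD is between donors and does not measure the difference between sites of a donor.

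At sites given sole fibroblasts, the collagenous matrix list passed downward and the sebaceous gland and keratinocyte lists upward in a gene list test with a preset correlation. None passed with an estimated correlation (adjusted p = 0.679). That test compares members with other genes and does not test agreement between donors. Within donors the list means differed by -0.96 to 0.88 for collagens, -1.90 to 1.41 for sebaceous gland and -0.52 to 1.19 for the cornified envelope. The basal keratinocyte mean was higher in every donor (0.01 to 0.25). All 22 members of the list of fibrillar collagens and associated matrix had a negative log2 fold change (median -0.33). The list fell in limma's camera test with a preset correlation (adjusted p = 6.9e-05; adjusted p = 0.679 with an estimated correlation). COL14A1, a collagen that binds fibril surfaces, fell by 0.84 ± 0.23 on the log2 scale (SE, lower in 5 of 6 donors) and was the 1 member that passed when adjusted over the list alone. LUM, a proteoglycan of collagen fibrils, stood at -0.80 ± 0.27, and FMOD, a related proteoglycan, at -0.46 ± 0.15, and neither passed. Among markers of dermal fibroblast subsets FAP, a cell surface protease of activated fibroblasts, was lower in 4 of 6 donors and higher in 0 (log2 fold change -0.99 ± 0.21). It was the 1 of 26 members that passed when adjusted over the list alone, and it was near 0 at the vehicle sites of the fractionated donors (0.118 CPM ± 0.204, SD, n = 3). All 22 sebaceous gland genes were positive (median 0.46; camera adjusted p = 6.9e-05; adjusted p = 0.679 with an estimated correlation), with AWAT1 and AWAT2, wax ester synthases of sebocytes, at 1.35 ± 0.65 and 1.24 ± 0.62. The cornified envelope list rose in the camera test with 40 of 46 members positive (median 0.23, adjusted p = 1.8e-08; adjusted p = 0.679 with an estimated correlation), and so did the basal keratinocyte list with 12 of 14 (median 0.13, adjusted p = 5.2e-04; adjusted p = 0.679 with an estimated correlation). Examples were ALOXE3, a lipoxygenase of the skin barrier, at 0.47 ± 0.14, CASP14, a protease of cornifying cells, at 0.47 ± 0.17 and ITGB4, an integrin of hemidesmosomes, at 0.20 ± 0.07, the last 2 higher in 6 of 6 donors. Cytosolic ribosomal protein genes fell as a list (39 of 40 negative, median -0.17, adjusted p = 6.9e-05; adjusted p = 0.679 with an estimated correlation). Their median was -0.26 in the fractionated donors and -0.08 in the single-injection donors. In the fractionated libraries 28 of these 40 genes rose with the share of ribosomal RNA in a fit without site kind. The mean share was 35.4% at vehicle and 12.2% at sole fibroblast sites, so RNA composition was not excluded as a source of the fall. Replicate 2 of the fractionated groups had a lower share at the vehicle than at the sole fibroblast site (11.8% and 14.5%).

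The medians of these lists were then set side by side for the 2 schedules. The collagen and sebaceous medians were -0.56 and 1.01 in the single-injection donors and -0.0024 and -0.23 in the fractionated donors, and the cornified envelope medians were -0.08 and 0.68. The fractionated donors did not agree among themselves on the first 2 lists. Their list means differed from vehicle by -0.68, -0.36 and 0.88 for collagens and by 1.39, -1.90 and 0.48 for sebaceous gland. In each list 1 donor thus went against the direction of the single-injection donors. Schedule also stands for kit and donors here. The interaction with schedule passed in the preset camera test for all 3 lists (adjusted p = 3.3e-05, 3.3e-05 and 3.6e-14) and for none with an estimated correlation (adjusted p = 0.711, 0.895 and 0.377).

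Over all genes, the edgeR test called 1 of 17562 genes between sole fibroblast and vehicle sites, with 637 at an unadjusted p under 0.05 where chance gives 878. DESeq2 called 3 genes, and limma voom with sample quality weights called 322, of which 33 were higher and 289 lower. The gene called by edgeR was GTF2IP4 (adjusted p = 0.00272), a pseudogene copy of GTF2I that is named here after its value was seen. Its expected counts ranged from 0.81 to 1381 among the single-injection vehicle sites, where GTF2I held 6221 to 8430. The division of reads between near-identical copies leaves it uncertain. The lists of volar and wound-type keratins (6 of 6 members positive, median 0.23) and of distal HOX genes (4 of 8 positive, median 0.02) did not pass, with camera adjusted p of 0.35 and 0.588. KRT16, a keratin of palms, soles and wounds, stood at 0.45 ± 0.38, and HOXC10 and HOXA10, transcription factors of the lower body, at -0.30 ± 0.14 and -0.29 ± 0.15. The list of WNT pathway inhibitors and targets had a median of 0.03 (adjusted p = 0.546), with SFRP2, a secreted WNT modulator, at -0.81 ± 0.32. Hair follicle, antimicrobial, endothelial and immediate early gene lists passed the preset camera test upward (adjusted p = 0.0305, 0.0266, 0.0419 and 0.0169), none with an estimated correlation (adjusted p = 0.679 for each). The hair follicle median was 2.47 as fitted and 0.31 from pooled counts in the single-injection donors and -2.02 and -1.73 in the fractionated donors (interaction adjusted p = 3.8e-21; adjusted p = 0.377 with an estimated correlation). The endothelial call came with replicate 3 of the fractionated groups, whose list mean differed by 1.60, while the other 5 donors lay between -0.10 and 0.04. In all, 7 lists passed upward and 2 downward of 29.

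At sites given scalp fibroblasts, the lists of keratinocyte alarm genes and adipocyte genes passed upward against vehicle sites in the preset camera test, and matrix lists passed downward. None passed with an estimated correlation (adjusted p = 0.397 to 0.425), and the adipocyte difference was seen in the single-injection donors. S100A7A, an antimicrobial S100 protein, had a log2 fold change of 4.56 ± 0.83 (SE, higher in 5 of 6 donors), and SERPINB4 and SERPINB3, protease inhibitors of inflamed epidermis, had 3.75 ± 0.95 and 1.04 ± 0.34. S100A7A was near 0 at the single-injection vehicle sites (0.0350 CPM ± 0.0419, SD, n = 3) and uneven at their scalp fibroblast sites (3.18 ± 5.44), which leaves the size of its change uncertain. S100A7A, SERPINB4 and SERPINB3 were the 3 of 12 members of the antimicrobial list that passed when adjusted over the list alone. The list had a median of 0.96 (camera adjusted p = 2.5e-07; adjusted p = 0.397 with an estimated correlation). In 1 of 3 single-injection donors the mean of this list was higher, against 3 of 3 fractionated donors. Of 19 adipocyte genes 16 were positive (median 0.68, adjusted p = 0.0025; adjusted p = 0.425 with an estimated correlation). The median was 0.77 in the single-injection donors and -0.14 in the fractionated donors, in whom 10 of 19 genes were near 0 counts in a group (interaction adjusted p = 5.7e-04; adjusted p = 0.796 with an estimated correlation). The 4 that passed when adjusted over the list alone were LPL, a lipase of fat cells, at 0.91 ± 0.19 in 6 of 6 donors, LEP, the hormone leptin, at 1.37 ± 0.39 in 3 of 6 donors, PLIN1, a lipid droplet coat protein, at 0.87 ± 0.28, and RBP4, a retinol carrier, at 1.02 ± 0.34. All 22 members of the collagen list and all 15 of the elastic fibre list were negative (medians -0.36 and -0.39, adjusted p = 1.7e-06 and 8.9e-05; adjusted p = 0.397 and 0.425 with an estimated correlation). LUM and COL5A1, a regulator of collagen fibril width, were lower in 6 of 6 donors at -0.74 ± 0.26 and -0.45 ± 0.16. LUM was low at the vehicle sites of the fractionated donors (1.23 CPM ± 1.07 against 819 ± 344 in the single-injection donors, SD, n = 3). Its direction in the fractionated donors therefore rests on few counts.

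The edgeR test called 0 of 17562 genes between scalp fibroblast and vehicle sites, with 547 at an unadjusted p under 0.05; DESeq2 called 0 and limma voom with sample quality weights called 130, 53 of them higher and 77 lower. Other lists that passed the preset camera test upward were the cornified envelope (median 0.24, adjusted p = 1.2e-07), sebaceous gland (0.50, 1.2e-05), basal keratinocyte (0.06, 0.0183), interferon response (0.41, 0.00268), proliferation (0.13, 0.047) and immediate early lists (0.09, 0.047). Those downward were hair follicle (-0.41, 0.00108) and wound and scar matrix (-0.19, 0.00268). The hair follicle median was 0.95 as fitted and 1.13 from pooled counts in the single-injection donors, and -2.73 and -2.00 in the fractionated donors. The mean of the interferon list was higher in 3 of 6 donors, with a difference of 0.40 ± 1.20 (SD, n = 6). None of the 12 lists passed with an estimated correlation, where the smallest adjusted p was 0.397. The volar keratin and distal HOX lists had medians of -0.06 and -0.12 and did not pass (adjusted p = 0.713 and 0.227), nor did WNT inhibitors and targets (-0.04, 0.275).

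Between sole and scalp fibroblast sites of the same donors, the adipocyte and antimicrobial lists passed downward in the preset camera test, and neither did with an estimated correlation (adjusted p = 0.621). Of 19 adipocyte genes 17 were negative (median -0.59, camera adjusted p = 0.00981; adjusted p = 0.621 with an estimated correlation). The fall rests on the single-injection donors, with a median of -0.68 against -0.0045 from pooled counts in the fractionated donors, in whom 9 of 19 genes were near 0 counts in a group (interaction adjusted p = 3.1e-06; adjusted p = 0.313 with an estimated correlation). Of the 17 5 passed downward when adjusted over the list alone, among them CD36, a fatty acid transporter, at -0.44 ± 0.11 (lower in 6 of 6 donors), LPL at -0.67 ± 0.20 (lower in 4) and PLIN1 at -0.81 ± 0.28 (lower in 5). S100A7A (-2.41 ± 0.71, lower in 3 of 6 donors and higher in 3), SERPINB4 (-2.46 ± 0.84, lower in 5) and PI3, an elastase inhibitor (-1.05 ± 0.37, lower in 5), were the 3 antimicrobial genes that passed when adjusted over the list alone (list median -0.75, adjusted p = 0.00288; adjusted p = 0.621 with an estimated correlation). Hair follicle genes had a positive fitted change in 30 of 32 (median 1.30, adjusted p = 2.2e-11; adjusted p = 0.621 with an estimated correlation), but the direction depended on the estimate. In the single-injection donors the median was 1.67 as fitted and -0.82 from pooled counts, and TCHH, a protein of the inner root sheath, had a mean of 56.3 CPM at sole and 98.7 CPM at scalp fibroblast sites. FOXN1, a transcription factor of hair and epidermis, stood at 0.28 ± 0.12 in 6 of 6 donors. The volar keratin, distal HOX and WNT lists had medians of 0.30, 0.02 and 0.03 (adjusted p = 0.143, 0.551 and 0.0706). Elastic fibre and endothelial lists passed the preset camera test upward (medians 0.06 and -0.03, adjusted p = 0.016 and 0.0072), and interferon response and ribosomal protein lists downward (-0.38 and -0.11, 0.0357 and 0.00725). In the fractionated donors the endothelial and interferon means differed by 0.64 ± 1.07 and -0.92 ± 1.93 (SD, n = 3), so both lists were uneven between donors. None of the 7 lists passed with an estimated correlation (adjusted p of 0.621 or more). The edgeR test called 1 of 17562 genes, again GTF2IP4 (adjusted p = 0.0039), with 221 at an unadjusted p under 0.05; DESeq2 and limma voom with sample quality weights called 1 each.

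Each schedule was then tested with its own site effects. In the single-injection donors the collagen list fell at sole fibroblast sites, with 0 of 22 members positive, a median of -0.56 and 9 members that passed when adjusted over the list alone (camera adjusted p = 1.8e-20; adjusted p = 0.0786 with an estimated correlation). ASPN, DCN and SPARC, proteins that bind collagen, stood at -0.997, -0.64 and -0.71. Within donors the mean of the list changed by -0.57 ± 0.36 (SD, n = 3) at sole and -0.43 ± 0.20 at scalp fibroblast sites, while the endothelial list changed by -0.05 ± 0.05 and 0.02 ± 0.05. Sebaceous gland genes were positive in 22 of 22 at both cell sites (medians 1.01 and 0.997; adjusted p = 0.132 and 0.163 with an estimated correlation), with ELOVL3, a fatty acid elongase, at 1.65 ± 0.39 at sole fibroblast sites. The adipocyte list rose at scalp fibroblast sites, with 18 of 19 members positive and 8 that passed when adjusted over the list alone (median 0.77; adjusted p = 0.0339 with an estimated correlation), and 19 of 19 were negative between sole and scalp fibroblast sites (median -0.68; adjusted p = 0.021 with an estimated correlation). These were the 2 list results that passed with an estimated correlation, and neither passed with fry (adjusted p = 0.529 and 0.583). Both rest on the same 3 scalp fibroblast libraries, so they are not independent. The adipocyte median for sole versus vehicle was 0.05. Hair follicle genes stood higher at sole fibroblast sites in 2 of 3 donors (fitted median 2.47, and 0.31 from pooled counts; adjusted p = 0.081 with an estimated correlation).

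In the fractionated donors the cornified envelope list rose at both cell sites, with 43 and 39 of 46 members positive, medians of 0.68 and 0.53, and 19 and 14 members that passed when adjusted over the list alone (camera adjusted p = 1.7e-14 and 2.5e-09; adjusted p = 0.551 and 0.632 with an estimated correlation). LCE1C, a protein of the late cornified envelope, stood at 1.13, and CDSN, an adhesion protein of the outermost layers, at 0.99 at sole fibroblast sites. The antimicrobial list had medians of 0.82 and 1.25 (adjusted p = 0.996 and 0.632 with an estimated correlation). At scalp fibroblast sites of these donors the collagen median was -0.29 and the sebaceous median 0.03. At both cell sites the mean of the collagen list was lower, and that of the sebaceous list higher, in 2 of 3 donors. The vehicle libraries of these donors held 11.8% to 51.7% ribosomal RNA, the scalp fibroblast libraries 1.88% to 47.3% and the sole fibroblast libraries 1.07% to 20.96%. The edgeR test called 1, 0 and 1 genes in the single-injection donors for sole versus vehicle, scalp versus vehicle and sole versus scalp (448, 236 and 90 at an unadjusted p under 0.05 of 17929, where chance gives 896). It called 0 in each comparison of the fractionated donors (2017, 2076 and 1018) and 0 for each difference between schedules (1283, 1255 and 551). This fit shared 1 estimate of the spread over the libraries of both kits, so its p-values need not match the spread of either schedule. DESeq2 called 18, 0 and 3 genes, then 115, 155 and 18, then 46, 11 and 8, and limma voom with sample quality weights called 608, 153 and 0, then 0 in all of the rest. Without replicate 2 of the fractionated groups the edgeR test called 489 genes for sole versus vehicle and 1277 for scalp versus vehicle in the fractionated donors.

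**Figure D2:**
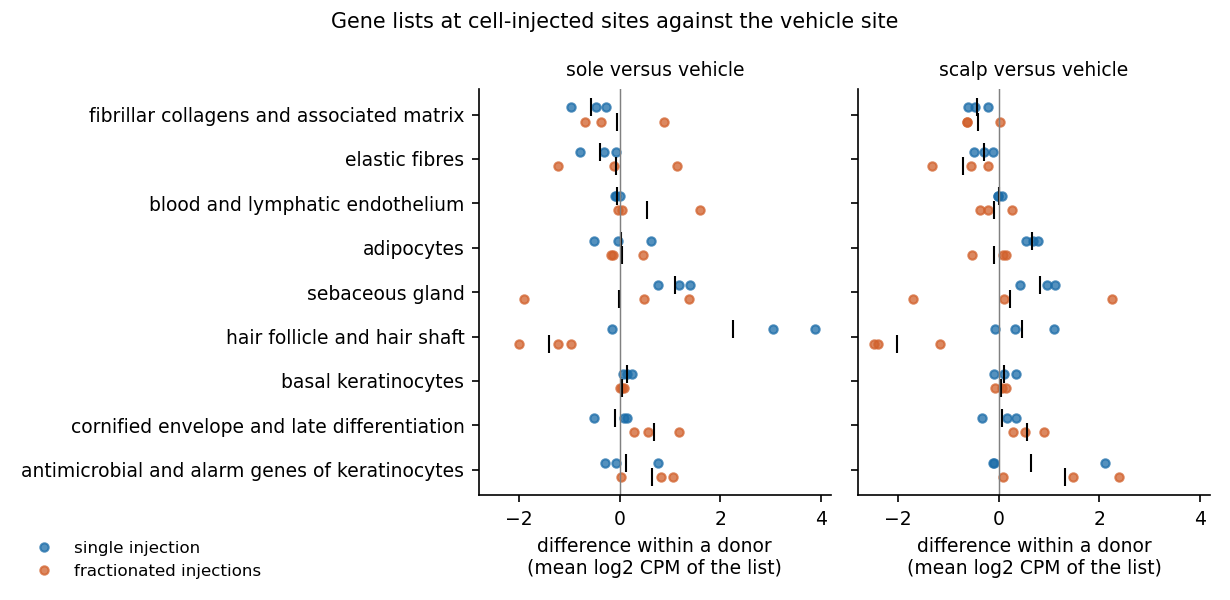
Difference between a cell-injected site and the vehicle site of the same donor in the mean log2 CPM of 9 gene lists, for sole (left) and scalp fibroblast sites (right). Points are donors, coloured by schedule, and black marks are means of 3 donors; the collagen list was below 0 in 3 of 3 single-injection donors at both cell sites, and the cornified envelope list above 0 in 3 of 3 fractionated donors.

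Across genes, the changes seen in 1 schedule bore little relation to those in the other. The Spearman correlation across 17562 genes, which are not independent replicates, was -0.0031 for sole versus vehicle, 0.04 for scalp versus vehicle and 0.05 for sole versus scalp. Each lay within the range of the 16 relabellings of sites within donors (-0.12 to 0.08, -0.17 to 0.17 and -0.15 to 0.11). Sole versus vehicle and scalp versus vehicle changes, which share the vehicle libraries, correlated at 0.59, where simulated unchanged groups gave 0.46, and their covariance was 0.060 where the simulation gave 0.028. Sole in the single-injection donors against scalp in the fractionated donors, which share no library, gave -0.06, and the converse gave 0.06. Between different donors of 1 schedule, which also share no library, the 6 pairs had a median Pearson correlation of 0.105 (0.0234 to 0.324) in the single-injection donors and -0.0076 (-0.130 to 0.188) in the fractionated donors. The simulation of unchanged groups used the trend of the spread over the libraries of both kits. It left out spread particular to a gene, a kit or the ribosomal RNA share. The size of the excess over it is therefore uncertain, and its source was not resolved.

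The vehicle sites, which received no cells, differed widely between the donors of the 2 schedules. The genes named here were chosen after their values were seen. COL1A1 and COL3A1, the main fibrillar collagens of the dermis, stood at 13649 CPM ± 3386 and 25109 ± 1118 (SD, n = 3) in the single-injection donors and at 37.2 ± 30.8 and 22.8 ± 25.6 in the fractionated donors. PECAM1, an endothelial adhesion protein, stood at 195 ± 49.8 against 0.723 ± 0.534 CPM, and ACTA2, a smooth muscle actin, at 155 ± 36.4 against 3.00 ± 1.03. KRT10 and KRT1, keratins of upper epidermal layers, were higher in the fractionated donors at 46286 ± 5170 against 5570 ± 781 CPM and 24265 ± 9238 against 3065 ± 790. Also higher were CD207, a marker of Langerhans cells (61.4 ± 21.3 against 18.8 ± 8.69), and MKI67, a proliferation marker (94.2 ± 29.8 against 22.3 ± 12.8). FLG of the cornified envelope list had a lower mean, at 5471 ± 2858 against 13333 ± 6217 CPM, without passing (edgeR adjusted p = 0.0532). MLANA, a melanocyte marker, stood at 20.6 ± 7.05 against 18.7 ± 9.27. The melanocyte genes PMEL and TYRP1 had lower means, at 46.6 ± 16.6 against 95.4 ± 72.9 and 117 ± 42.4 against 244 ± 203, and neither passed the threshold. By list, 21 of 22 endothelial, 21 of 22 collagen and 10 of 10 mast cell genes were lower, and 12 of 14 basal keratinocyte and 23 of 45 cornified envelope genes higher, at an edgeR adjusted p under 0.05 over all genes. With group totals of at most 3 counts set to 3 counts, pooled counts put the median member 266-fold lower for endothelium and 289-fold lower for mast cells. For the collagen list, in which no member was at that floor, they put it 99.9-fold lower. These folds are per total count, ribosomal RNA included, without TMM. The TMM fit gave 68.1-fold for the collagen list, so the pooled folds are not lower bounds. With an estimated correlation no list passed in the camera test (smallest adjusted p = 0.153). The edgeR test called 8513 of 16554 genes, 3797 higher and 4716 lower in the fractionated donors; DESeq2 called 9101 and limma voom with sample quality weights 8632. Kit, schedule and donors cannot be told apart in this comparison.

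**Figure D3:**
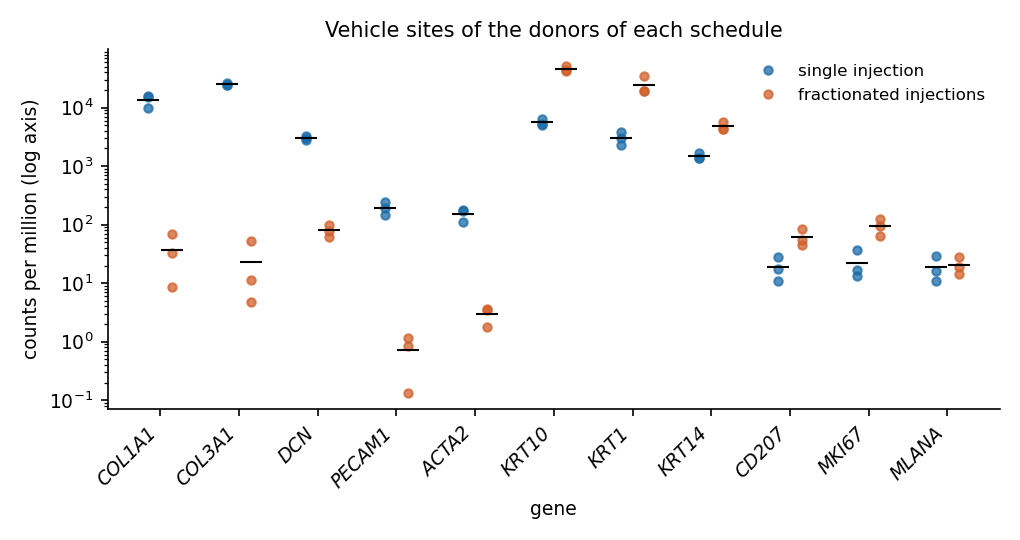
CPM (log axis) of 11 genes at the vehicle sites of the single-injection and the fractionated donors. Points are libraries and black marks are means of 3; the genes from COL1A1 to ACTA2 lie lower in the fractionated donors and those from KRT10 to MKI67 higher, with MLANA at 18.7 and 20.6 CPM.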

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

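The tests of the endothelial list in the weighing of the collagen list were chosen after that result was seen. The tests with ribosomal RNA as a covariate were also added after the data had been examined, with the bounds for them set before their own results were seen.

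A total of 24 list results differed between the 2 schedules in the camera test of the interaction with a preset correlation, and none did with an estimated correlation (adjusted p of 0.313 or more). Values are median log2 differences, fractionated minus single-injection donors. For sole versus vehicle they were 0.70 for the cornified envelope, -4.74 for hair follicle, -1.26 for sebaceous gland, 0.52 for fibrillar collagens and 0.99 for endothelium. For scalp versus vehicle they were -1.30 for volar and wound-type keratins, 0.45 for the cornified envelope, 0.40 for antimicrobial genes, -3.42 for hair follicle, -0.84 for sebaceous gland, 0.48 for melanocytes, -0.76 for adipocytes and 1.65 for interferon response. For sole versus scalp they were 0.14 for the cornified envelope, -0.74 for hair follicle, -0.32 for melanocytes, 0.42 for fibrillar collagens, 0.76 for elastic fibres, 0.49 for wound and scar matrix, 0.43 for dermal fibroblast subsets, 0.77 for adipocytes, 1.49 for endothelium, -1.37 for interferon response and -0.24 for ribosomal proteins. Many members of the dermal lists were near 0 counts in the fractionated donors, 15 of 22 for endothelium in sole versus vehicle and 10 of 19 for adipocytes in scalp versus vehicle. The endothelial difference of sole versus vehicle came with replicate 3 of the fractionated groups, whose list mean differed by 1.60 against -0.02 and 0.04 in the others. The interferon differences rest on uneven scalp fibroblast libraries of the fractionated donors, where IFI44L stood at 13.7 CPM ± 22.5 (SD, n = 3), IFI44 at 8.35 ± 13.4 and OAS2 at 31.3 ± 43.6. From pooled counts with group totals of at most 3 set to 3, the endothelial medians were 0.55 for sole versus vehicle and 0.42 for sole versus scalp, the adipocyte medians -0.59 for scalp versus vehicle and 0.66 for sole versus scalp, and the hair follicle medians -1.97 for sole versus vehicle, -3.15 for scalp versus vehicle and 1.16 for sole versus scalp, the last of opposite sign to the fitted median. The same floor gave -1.38 and -0.96 for sebaceous gland in sole and scalp versus vehicle and 1.63 and -1.74 for interferon response in scalp versus vehicle and sole versus scalp. In sole versus scalp it gave 0.83 for elastic fibres, 0.39 for wound and scar matrix and 0.33 for dermal fibroblast subsets. The other lists had no member at the floor, and pooled counts gave them 0.55 (cornified envelope) and 0.35 (collagens) for sole versus vehicle. For scalp versus vehicle they gave 0.25 for the cornified envelope, 0.14 for antimicrobial genes, -1.71 for volar and wound-type keratins and 0.35 for melanocytes. For sole versus scalp they gave 0.20 for the cornified envelope, -0.25 for melanocytes, 0.39 for collagens and -0.23 for ribosomal proteins. The edgeR test called 0 genes for each interaction (1283, 1255 and 551 at an unadjusted p under 0.05), where DESeq2 called 46, 11 and 8 and limma voom with sample quality weights 0. In each interaction 10 of 10 splits of the donors gave a count as large, with 0 as the highest of the others, which a real count of 0 fixes in advance, and 10 splits are too few for a share under 0.05.

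The lower collagen list at cell-injected sites of the single-injection donors could come from a smaller share of dermis in those biopsies. That would lower the endothelial list too, and its mean within-donor difference was -0.054 for sole versus vehicle and 0.015 for scalp versus vehicle (SE 0.029 and 0.026, n = 3), each above -0.28 and -0.21, which is 50% of the collagen difference. The endothelial values argue against a smaller share of all dermis as the whole cause. Other values go with it: mast cell genes had medians of -0.24 and -0.26 and macrophage and dendritic cell genes -0.20 and -0.22 for sole and scalp versus vehicle. LYVE1 and PDPN, among 22 members of the endothelial list, stood at -0.95 and -0.47 for sole versus vehicle. Further lists were mixed. Elastic fibres (-0.42 and -0.37) and dermal fibroblast subsets (-0.21 and -0.20) fell. Smooth muscle and pericyte (0.13 and 0.01), nerve and Schwann cell (-0.04 and 0.03) and T and NK cell medians (0.10 and -0.02) lay near 0. Adipocyte medians were 0.05 and 0.77. A smaller share of dermis as part of the cause, more sebaceous gland in the biopsies (within-donor mean 1.11 ± 0.33 and 0.83 ± 0.37, SD) and an effect of the cells remain open, and the last 2 were not tested.

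The higher cornified envelope genes at cell-injected sites of the fractionated donors could come from the ribosomal RNA in their vehicle libraries. With the ribosomal RNA share as a covariate the difference of the list mean was 0.59 ± 0.26 (SE) for sole versus vehicle, against 0.64 ± 0.20 without it. It lay barely more than 1 SE above 50% of the value without it (0.32). For scalp versus vehicle it was 0.45 ± 0.24 against 0.49 ± 0.20, within 1 SE of 50% of the value without it (0.24). With 3 residual degrees of freedom the test is too weak to decide. The pairs of replicate 2 went against ribosomal RNA as the whole source. Its share was 11.8% at the vehicle, 14.5% at the sole fibroblast and 47.3% at the scalp fibroblast site. The list mean was still higher by 0.28 and 0.51 at the cell sites. As this is 1 donor of 3, ribosomal RNA and an effect of the cells cannot be told apart in either comparison. The depth of epidermis in each biopsy was not measured.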

How the results depend on the processing

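The alternatives with ribosomal and structural RNA left out, with the 3 libraries over 40% ribosomal RNA left out, and with the ribosomal RNA share as a covariate were chosen after seeing the data. The count at vehicle sites ranged from 6119 to 9787 over the alternatives fixed before the data were seen, and KRT9 for sole versus vehicle from 0.08 to 0.27 over all settings but those that left out a donor. Depth limits genes of low count in the fractionated donors, and the cause of the differences below was not tested except where fewer libraries or genes entered.

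By DESeq2, 3 genes changed for sole versus vehicle, in the single-injection donors 18 for sole versus vehicle and 3 for sole versus scalp, in the fractionated donors 115, 155 and 18, and between schedules 46, 11 and 8; LYVE1 for sole versus vehicle turned to 0.35. By limma voom with sample quality weights, 322 and 130 genes changed for sole and scalp versus vehicle, 608 and 153 in the single-injection donors, and 0 there for sole versus scalp. Signs turned with voom for KRT9 (0.088), KRT72 (-0.082) and LOXL1 (-0.11) in sole versus scalp, and for KRT6C (0.43), KRT6B (0.21), LHX2 (0.50), KRT75 (0.64), TCHH (0.16), OAS2 (-0.012) and IFI44 (-0.069) in scalp versus vehicle.

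With a filter of 1 CPM in 6 libraries the counts of 1 gene (sole versus vehicle and sole versus scalp, over all donors and in the single-injection donors) became 0, because GTF2IP4 was no longer tested, and the correlation of sole versus vehicle changes between schedules was 0.00056. Pearson in place of Spearman turned that of scalp versus vehicle to -0.0084. With no filter 5 lists passed for sole versus vehicle. Over all donors, camera with an estimated correlation and fry passed 0 lists in each comparison. In the single-injection donors camera with an estimated correlation passed 1 list for scalp versus vehicle and 1 for sole versus scalp, and fry passed 0. On only the libraries compared, 0 genes changed for sole versus vehicle and sole versus scalp, and within schedules 5 (single, sole versus vehicle), 0 (single, sole versus scalp), 1 and 1 (fractionated, sole and scalp versus vehicle).

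With no replicate block, and the kit in place of the donor, 0 genes changed for sole versus vehicle and sole versus scalp, over all donors and in the single-injection donors, where the donor pairing of the block gave 1 each. The signs of KRT81 (-0.71), KRT33A (-0.63) and KRT35 (-0.46) turned for sole versus vehicle, of KRT6B (0.12) for scalp versus vehicle, and of TCHH (-0.093) and KRT74 (-0.32) for sole versus scalp; no other count of genes or lists left the range of 1.5 times.

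With ribosomal RNA as a covariate 1 gene, S100A7A, changed for scalp versus vehicle, 6 and 3 in the fractionated donors for scalp versus vehicle and sole versus scalp, and 2 and 3 between schedules. With structural RNA left out 0 genes changed for sole versus scalp in the single-injection donors. Without the libraries over 40% ribosomal RNA, 3 lists passed for sole versus scalp, 2 genes changed for sole versus vehicle in the single-injection donors, 4, 14 and 1 in the fractionated donors, and 2, 7 and 1 between schedules. Signs turned there for KRT75 (0.36), TCHH (0.79), OAS2 (-0.045), IFI44 (-0.080) and AURKB (0.21) in scalp versus vehicle, and for KRT9 (0.13), RPS20 (0.0038) and RPS13 (0.022) in sole versus scalp.

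With 1 donor left out at a time, counts of genes ranged from 0 to 2 (sole versus vehicle) and 0 to 1 (sole versus scalp), in the single-injection donors from 0 to 9 and 0 to 7, in the fractionated donors from 0 to 489 (sole versus vehicle), 0 to 1277 (scalp versus vehicle) and 0 to 1 (sole versus scalp), and between schedules from 0 to 16, 0 to 1 and 0 to 1. The 489 and 1277 genes came without replicate 2 of the fractionated groups, and the 9, 7 and 16 without replicate 1 of the single-injection groups. KRT9 ranged from -0.037 to 0.27 for scalp versus vehicle and from -0.20 to 0.12 for sole versus scalp. CXCL10 ranged from -0.20 to 1.88, KRT16 from -0.13 to 0.62, MFAP5 from -0.35 to 0.053 and RPS13 from -0.21 to 0.012 in sole versus scalp, and KRT6C from -0.28 to 0.62 in sole versus vehicle.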

Other observations

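The tests of ribosomal RNA share across genes, of transcript length along it, and the genes named in the fits of single schedules were chosen after related results were seen.

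Fitted on the 9 libraries of 1 schedule alone, edgeR called 5 genes for sole versus vehicle in the single-injection donors. These were ANGPTL2, a secreted angiopoietin-like protein, at -0.80 ± 0.09 (log2 fold change, SE), ABCB5, a membrane transporter, at -0.99 ± 0.12, FASN, the fatty acid synthase, at 0.64 ± 0.08, RGPD8 at 0.77 ± 0.09 and GTF2IP4, each at an adjusted p of 0.0415; RGPD8 and GTF2IP4 have near-identical copies and are uncertain. In the fractionated donors the same fit called KRT85, a keratin of the hair shaft, at -3.51 ± 0.44 for sole versus vehicle (adjusted p = 0.0478) and -4.23 ± 0.48 for scalp versus vehicle (adjusted p = 0.0163). Hair follicle genes as a list were lower than at the vehicle site in 3 of 3 fractionated donors at both cell sites. Among lists with at least 3 members in a fit without site kind, they had the largest median slope on the ribosomal RNA share of these libraries. It was 0.37 on the log2 scale per 10 percentage points, with 7 of 25 genes up and 0 down. The mean share was highest at vehicle sites (35.4%). The pairs of replicate 2 went against RNA composition as the whole source, since its share was 11.8% at the vehicle, 14.5% at the sole fibroblast and 47.3% at the scalp fibroblast site, while the list mean was lower by 0.97 and 1.17 at the cell sites. As this is 1 donor of 3, RNA composition is left open for the fall.

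Chance was weighed by relabelling sites within donors. For sole versus vehicle 10 of 32 splits called as many genes as the real one (1, highest other 1) and 13 passed as many lists (9, highest other 13). For scalp versus vehicle 2 of 32 passed as many lists (12, highest other 12), and for sole versus scalp 16 called as many genes (1, highest other 1) and 25 passed as many lists (7, highest other 13). Chance is therefore not excluded for any of these counts. For scalp versus vehicle the real count of genes was 0 (547 at an unadjusted p under 0.05 by edgeR), so that 32 of 32 splits had to match it (highest other 0), which says nothing about chance. The 322 and 130 genes of limma voom with sample quality weights were matched in 3 of 32 splits each (highest other 360 and 209). The 8 splits that left the single-injection donors as labelled gave 278 to 360 and 45 to 209 genes, and the other 24 gave 0 to 6 and 0 to 5, so those calls rest on the labels of the 3 single-injection donors, whose libraries had a mean weight of 1.73 against 0.766. Within a schedule 4 splits exist, too few for a share under 0.05. In the single-injection donors 2, 4 and 2 of them matched the real counts of 1, 0 and 1 for sole versus vehicle, scalp versus vehicle and sole versus scalp (highest others 1, 0 and 1). In the fractionated donors 4, 4 and 4 matched the real counts of 0, with highest others of 5, 2114 and 2, and a match to a count of 0 is again fixed in advance. At vehicle sites 1 of 10 splits, the real one, gave 8513 genes, and the highest other gave 0; 10 splits are also too few.

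The split of the fractionated scalp fibroblast and vehicle libraries that called 2114 genes swapped the sites of replicate 2 and so set the library with more ribosomal RNA of each donor against the one with less, which points to a structure of these libraries. Across the 9 fractionated libraries, with donor as a block, 1134 genes rose and 1160 fell with the ribosomal RNA share, and in the single-injection libraries 0 did by edgeR (413 at an unadjusted p under 0.05). With site kind also in the fit of the fractionated libraries, 690 rose and 607 fell. The slopes that follow are from the fit without site kind, so they can hold site differences. Of 40 ribosomal protein genes 28 rose with the share (median 0.13 on the log2 scale per 10 percentage points), and of 45 cornified envelope genes 2 rose and 11 fell. A bias by transcript length could account for part of this: the median slope was 0.11 for 1398 genes under 1000 bases and -0.04 for 6508 genes over 3000 bases, a difference of 0.15. RNA quality or amplification differences as sources of it were not tested.

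The near absence of dermal transcripts at the fractionated vehicle sites could come from the kits or from the tissue. A length bias between the kits would be removed by a trend on effective length, and the median of 128 dermal list genes was -5.61 after that trend was removed and -6.17 before, which argues against it as the whole cause. Lower depth would leave genes near their predicted counts, and 89.7% of 126 dermal list genes predicted at 10 or more counts per library lay below 25% of the prediction, which argues against depth. The kit as such, the piece of skin taken, the donors and the schedule cannot be told apart, since 0 fractionated vehicle libraries were made with the other kit. Melanocyte genes, which belong to the epidermis, had a median of -0.28 as fitted and -0.86 from pooled counts without TMM. KRT10, KRT1, CD207 and 12 of 14 basal keratinocyte genes were higher at an edgeR adjusted p under 0.05. Of 6 volar and wound-type keratins 0 passed that threshold, with a median of 0.56 as fitted and -0.12 from pooled counts without TMM. A larger share of epidermis is left open.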
